A study of Mus musculus with 9 samples.

How the data were processed

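Whole mouse retinas were profiled by bulk RNA sequencing in 9 libraries, 3 for each of 3 groups. Per the labels, each P60 library came from 1 frozen retina, and libraries were made from 1 µg of total RNA with a directional TruSeq protocol, which keeps the strand of the transcript. The submitters' processing notes name HISAT2 2.1.0, featureCounts, edgeR and the genome build GRCm38. The version of featureCounts, the annotation release and the strand setting used in counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart with certainty.

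The deposited count table gave whole-number read counts, not normalized, for 47729 Ensembl gene identifiers in the 9 libraries. A symbol was found for 47224 of the identifiers, and 47310 were present in GENCODE M21, which is built on GRCm38 and from which the positions given here were taken. The authors' deposited comparison table held 305 genes with a log2 fold change, a p-value and an adjusted p-value for each of the 3 comparisons, per the file headers. The 9 columns of that table with values per library and its 5 columns of group means were not used. One C57 column carried a number that no sample description shares, while the remaining C57 description carries another number. That column was kept in the C57 group because its name gives a wild-type retina. It is called the unnumbered C57 library, and which sample it holds remains uncertain.

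Total counts were 13760765 to 16808499 in the C57 libraries and 34739679 to 37629264 in the P60 libraries. For each of the 3 comparisons, the 6 libraries concerned were fitted alone. Genes were kept with filterByExpr (minimum count 10, minimum total 15), and libraries were scaled by TMM. Then edgeR 4.0.16 quasi-likelihood F-tests with robust estimation (R 4.3.3) gave log2 fold changes, standard errors and p-values, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p of a gene comes from this edgeR test unless another tool is named. Normalized counts (CPM) are TMM-scaled within the 6 libraries of the comparison, so the same group has slightly different CPM in different comparisons. The groups, the tests, the 34 gene lists, the processing alternatives and the rule for naming genes were fixed before the data were examined. The fixed design did not name edgeR's choice between its older quasi-likelihood statistics and the bias-adjusted deviances. The package default of the installed version (the older statistics) was kept after the counts under both had been seen, and the other choice is reported among the alternatives.

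Gene lists of at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. The fry test, which asks whether the members of a list moved in a common direction and does not compare them with other genes, was run beside it. A list whose members changed in opposite directions can therefore miss the threshold by fry. The named genes were Yap1, Wwtr1 and Rax, the 12 genes per direction with the largest change among those that passed without overlap between libraries and with a mean of at least 5 CPM in the higher group (predicted genes, clones and pseudogenes left out), up to 4 members per list with the smallest p, the 3 genes per direction with the smallest p, and for lists that describe sample composition the 3 members with the highest level. Where fewer than 6 genes per direction qualified by size, the 6 with the smallest p were taken instead, whether or not they passed. Most but not all genes that the rule selects are described.

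Alternatives were RLE and upper-quartile scaling, TMM without the 50 highest genes, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, one fit over all 9 libraries, other thresholds, the replicate number as a block, and leaving out each library in turn. For overlaps between comparisons that share libraries, 30 data sets without any group difference were simulated. Lists of the observed sizes were then taken by smallest p from each, a step added after seeing the data. Chosen after seeing the data were also a rod level covariate, a sex covariate, the bias-adjusted deviances, and random thinning of the P60 libraries to the depth of the shallowest C57 library. The test was tried on simulated data with known changes. For Yap CKO against control (16355 genes), edgeR recovered 34.3% of 1.5-fold, 83.6% of 2-fold and 95.5% of 4-fold changes (23 of 67, 56 of 67 and 63 of 66 genes). It made 18 false calls among unchanged genes, where DESeq2 made 44 and limma-voom 9. The shares were 20.9%, 70.1% and 97.0% for control against C57 (15581 genes, 13 false calls) and 4.48%, 53.7% and 93.9% for Yap CKO against C57 (15597 genes, 11 false calls). Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom between 24.2 and 144). None was thus the same library sequenced again, and all 9 were counted as separate samples. This cannot show that each retina came from a different animal.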

Results

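The retinas came from 3 groups of mice on a C57Bl6/J background, with 3 libraries each. Yap CKO mice carried floxed Yap and Rax-CreERT2, a tamoxifen-dependent Cre that deletes the floxed gene in Müller cells, the resident glia of the retina. Control mice carried floxed Yap without the Cre. Both groups received 4-hydroxytamoxifen at P10 and were examined at P60. The C57 group was wild type, taken at P30, and was re-analysed from an earlier series. The names of the control and Yap CKO libraries contain the letters MNU, while the labels describe no treatment of that name. The authors' deposited comparisons also carry MNU in the names of both P60 groups and not in that of C57. The genotype entry of the control samples reads Yap CKO without a Cre, and the design text was followed in calling them controls. The P60 libraries were sequenced to 34739679 to 37629264 counts and the C57 libraries to 13760765 to 16808499.

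The first principal component held 72.7% of the variance and separated the C57 libraries from the 6 P60 libraries. Rod photoreceptor markers were high and even in C57 (mean log2(CPM + 1) of 20 genes 11.7, 11.7 and 11.6) and lower and uneven at P60. They stood at 9.21, 7.07 and 8.26 in control 1, 2 and 3 and at 9.32, 8.48 and 5.47 in Yap CKO 1, 2 and 3. Reactive gliosis markers were at 3.05 to 3.35 in C57 and at 6.53 to 6.996 in the P60 libraries. Yap CKO 3 alone carried high lens transcripts, with a mean of 6.07 over 14 lens genes against at most 1.38 in any other library. Y-linked transcripts were present in all 3 controls, in Yap CKO 3 and in C57 2 (126 to 149 CPM), whereas Xist, the RNA of the inactive X chromosome, marked Yap CKO 1 and 2 and the other C57 libraries (117 to 230 CPM). The control retinas were thus all male, and of the Yap CKO retinas 2 were female and 1 was male. Males and females are counted below as retinas, since different animals cannot be shown. With sex as a covariate, the Yap CKO change is therefore estimated from Yap CKO 3 alone against the controls. Such a fit cannot tell sex from other traits of that library.

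**Figure D1:**
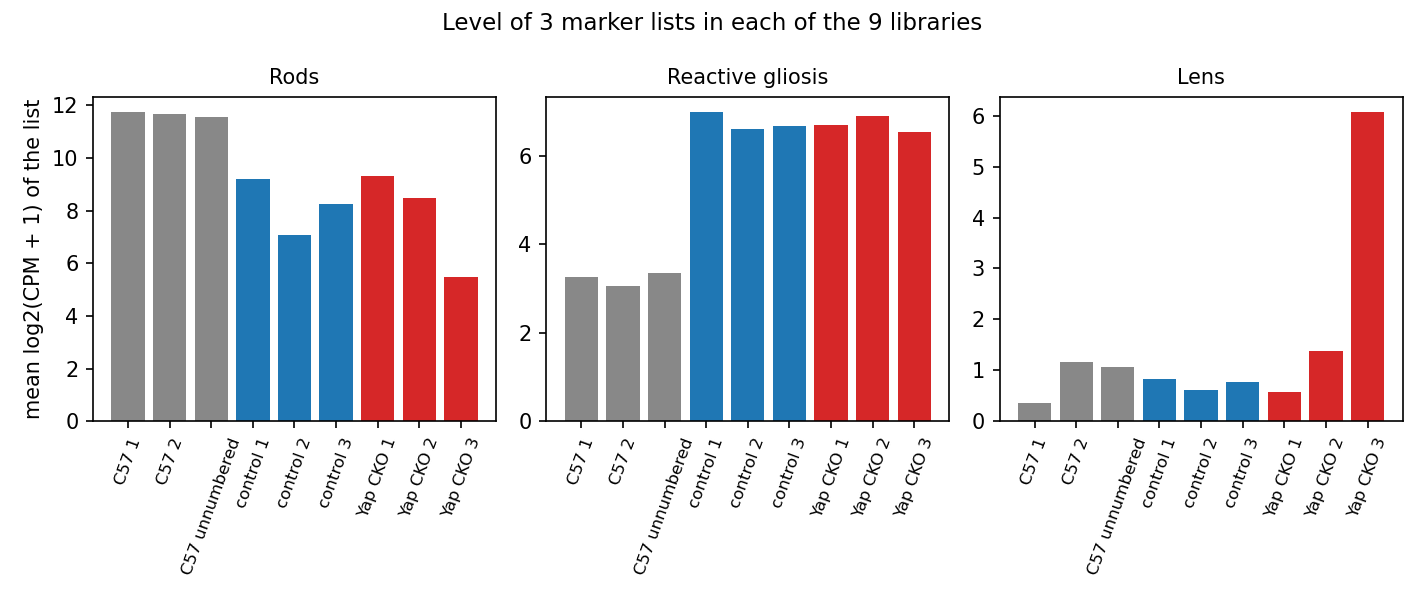
Bars give the mean log2(CPM + 1) of rod, reactive gliosis and lens marker genes in each of the 9 libraries, on axes that start at 0. Rod markers are lowest in Yap CKO 3 (5.47), which is also the library with high lens transcripts (6.07).

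The comparison of Yap CKO with control retinas sets P60 retinas with floxed Yap and Rax-CreERT2 against P60 retinas with floxed Yap alone. Besides the Yap deletion, the groups differ in the Cre allele itself and in sex, so the comparison does not isolate the loss of Yap. Yap1, the transcriptional coactivator targeted by the deletion (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, minus strand, GRCm38), fell 3.04-fold, from 66.7 ± 4.66 to 21.97 ± 4.996 CPM (SD, n = 3; log2 fold change -1.602, SE 0.166, adjusted p = 0.0327). Its levels were 71.6, 66.2 and 62.3 CPM in the controls and 16.4, 23.3 and 26.2 CPM in the Yap CKO libraries, counted over all exons. Counting Yap1, 30 genes fell and 3 rose among 16539 tested. The genes that fell included the monocyte-attracting chemokines Ccl2 and Ccl7, the leukocyte adhesion molecules Icam1 and Vcam1, the actin-associated genes Tagln and Cnn2, the EGFR ligand Hbegf and the AP-1 transcription factor Fosl1. Ccl2 dropped from 140 ± 30.6 to 32.5 ± 6.57 CPM (log2 -2.11, SE 0.204, adjusted p = 0.0369) and Icam1 from 110 ± 19.8 to 40.9 ± 4.35 CPM (log2 -1.42, SE 0.142, adjusted p = 0.0242; n = 3 per group).

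Among the other genes that fell, log2 fold changes were -1.82 for Ccl7, -1.75 for Tagln, -1.53 for Cnn2, -1.31 for Vcam1, -1.23 for Stx11, -1.21 for Arhgap22, -1.20 for Arrdc4, -1.13 for the activin inhibitor Fstl3 and -1.08 for Timp3, an inhibitor of matrix metalloproteinases (adjusted p between 0.0188 and 0.0496). Timp3 went from 366 ± 44.0 to 173 ± 10.4 CPM, and Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, from 45.9 ± 2.29 to 24.3 ± 1.53 CPM (n = 3 each). Slc43a3 had a log2 fold change of -2.08 at a low level (0.928 against 3.92 CPM). The genes that rose were Raxos1, an antisense transcript at the Rax locus (0.425 ± 0.231 to 3.85 ± 0.465 CPM, log2 3.16, SE 0.327, adjusted p = 0.0242), Dbi, which encodes the diazepam-binding inhibitor (log2 0.56), and the mitochondrial carrier gene Sfxn5 (log2 0.45, both with adjusted p = 0.0496). Raxos1 (chromosome 18, 65937538 to 65940447, plus strand) overlaps Rax (65928277 to 65939787, minus strand), so its counts are uncertain where the strand setting is unknown. Rax itself stood at 36.4 ± 6.80 against 29.1 ± 9.82 CPM (log2 0.33, adjusted p = 0.569). The next genes in the upward direction missed the threshold: Gfap, the intermediate filament of reactive glia, was at 685 ± 74.1 against 327 ± 62.4 CPM (log2 1.07, adjusted p = 0.0533), Npy had a log2 fold change of 0.94 (0.0533), Mrpl52 of 0.47 (0.0533) and Mmp12 of 1.596 (0.0553).

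**Figure D2:**
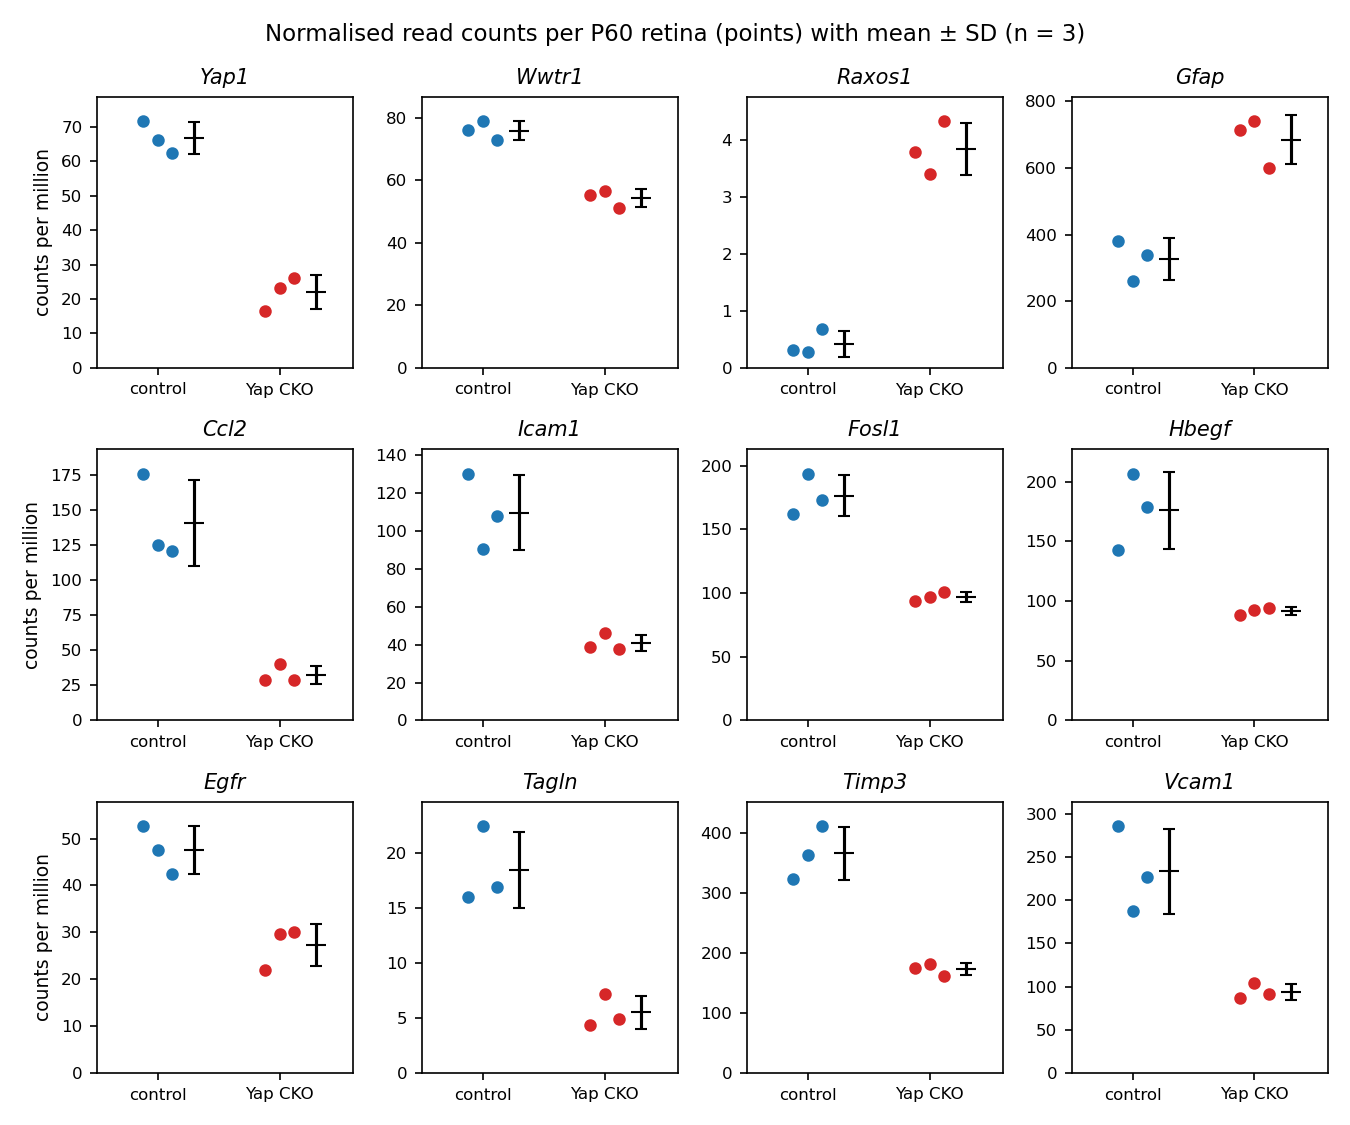
Points give TMM-scaled CPM of 12 genes in each of the 6 P60 retinas, with the mean ± SD of each group (n = 3) beside them. Yap1 is lower in each Yap CKO library (16.4 to 26.2 CPM) than in each control (62.3 to 71.6 CPM). Wwtr1, Gfap and Egfr did not pass the test over all genes.

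All 33 genes had no overlap between the groups, as did 4133 genes in all (24.99% of those tested, where chance gives 10%). At an unadjusted p under 0.05 the edgeR test found 2950 genes, and at an adjusted p under 0.10 it found 113 higher and 257 lower. The count changed widely with the tool and with single libraries. DESeq2 called 364 higher and 558 lower, and limma-voom 1 and 14. Leaving out Yap CKO 3 gave 656 and 817 by edgeR, among them all 33, but set 2 females against 3 males. Without control 1 or control 2 edgeR called 0 genes (2035 and 2226 at an unadjusted p under 0.05), without Yap CKO 1 it called 3 and without Yap CKO 2 it called 1 gene, all lower, and without control 3 it called 2 higher and 51 lower. Many of the 33 genes sat at an adjusted p of 0.0496, just under the threshold, and 15 of the 33 remained with RLE scaling, with a filter on CPM, with limma-voom or with the bias-adjusted deviances of edgeR. Yap1 missed the threshold without control 1 (adjusted p = 0.111), control 2 (0.106) or Yap CKO 2 (0.167), with log2 fold changes of -1.55, -1.61 and -1.65. It also missed with the replicate block (log2 -1.62, adjusted p = 0.0732). With sex as a covariate, chosen after seeing the data, it missed too, at log2 -1.35 for Yap CKO 3 alone against the controls.

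The gene groups linked to Yap leaned downwards by camera with the preset correlation. Of 17 Hippo pathway components, the upstream kinases and partners of Yap, 16 had negative log2 fold changes (median -0.19; camera adjusted p = 1.42e-05, adjusted p = 0.177 with an estimated correlation, fry adjusted p = 0.0134). None passed over all genes by edgeR (7 lower at an unadjusted p under 0.05, 6 lower by DESeq2, 0 by limma-voom), and 6 were lower when adjusted over the list alone. Wwtr1, which encodes the Yap paralog TAZ, was at 54.4 ± 2.80 against 75.9 ± 3.09 CPM (log2 -0.48, adjusted p = 0.0515), and Taok1, Lats1 and Mob1b had log2 fold changes of -0.40, -0.33 and -0.50 (adjusted p between 0.0647 and 0.0738). In a signature of YAP/TAZ target genes, 16 of 21 members were negative (camera adjusted p = 0.00359; adjusted p = 0.965 with an estimated correlation; fry adjusted p = 0.0939). The call was lost with sex as a covariate, where Yap CKO 3 alone stands against the controls, and sex and genotype were partly confounded. None of them passed over all genes by edgeR (6 lower and 1 higher at an unadjusted p under 0.05, 5 lower by DESeq2, 0 by limma-voom), while 6 were lower when adjusted over the list alone. Ccn1, Ptpn14, Axl and F3 had log2 fold changes of -1.27, -1.14, -1.03 and -0.47, with adjusted p from 0.0619 to 0.107.

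Genes of EGFR signalling lay lower as a group: 10 of 12 ligands and receptors were negative, with a median of -0.63 (camera adjusted p = 0.000138; adjusted p = 0.288 with an estimated correlation; fry adjusted p = 0.0268). Hbegf fell from 176 ± 32.0 to 91.8 ± 3.08 CPM (n = 3, adjusted p = 0.0496), and 5 members were lower when adjusted over the list alone. The receptor Egfr itself was at 27.2 ± 4.49 against 47.6 ± 5.06 CPM (log2 -0.80, adjusted p = 0.0676), the ErbB ligand Nrg1 at log2 -0.80 (0.0790) and Erbb4 at log2 -0.63 (0.130). Among 20 ERK feedback and immediate-early genes, Fosl1 fell from 176 ± 16.0 to 97.1 ± 3.90 CPM (log2 -0.86, adjusted p = 0.0188) and 19 did not pass, with 2 lower when adjusted over the list alone (camera adjusted p = 0.00702; adjusted p = 0.573 with an estimated correlation; fry adjusted p = 0.0916). Spry2 and Spred1, feedback inhibitors of this pathway, were at log2 -0.51 and -0.42 (adjusted p = 0.112 and 0.158).

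Inflammatory mediators were among the genes that fell. Of 16 chemokines and cytokines, Ccl2 and Ccl7 fell, 14 of 16 were negative and 7 were lower when adjusted over the list alone (camera adjusted p = 4.65e-05; adjusted p = 0.573 with an estimated correlation; fry adjusted p = 0.0916). Cxcl1 had a log2 fold change of -1.48 (adjusted p = 0.0746) and Csf1, a growth factor of microglia and macrophages, of -0.57 (adjusted p = 0.0879). Interferon-stimulated genes leaned the same way, with 14 of 15 negative and a median of -0.51 (camera adjusted p = 0.0301; adjusted p = 0.974 with an estimated correlation; fry adjusted p = 0.852). The call was lost without control 1 (adjusted p = 0.389), Yap CKO 1 (0.107) or Yap CKO 3 (0.127), and with the rod covariate (0.1197). With the sex covariate, which rests on Yap CKO 3 alone, it was lost too. None passed singly by edgeR, over all genes or adjusted over the list alone (2 lower at an unadjusted p under 0.05 and by DESeq2, 0 by limma-voom); Gbp2 was at log2 -1.59 (adjusted p = 0.152). Of 18 matrix genes 8 were positive and 10 negative. Lama5, a laminin chain, fell (log2 -0.71, adjusted p = 0.0496) and 17 did not pass, while 4 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0450; adjusted p = 0.974 with an estimated correlation; fry adjusted p = 0.699). This call was lost without control 2 (adjusted p = 0.0989) or Yap CKO 1 (0.514) and with the replicate block (0.0507). With sex as a covariate, which rests on Yap CKO 3 alone, the list pointed the other way. Among 15 markers of the neighbouring ciliary epithelium, a list chosen after seeing the data, 13 were negative (median log2 -0.62; 10 lower at an unadjusted p under 0.05), and several of them encode matrix proteins. Whether the lower matrix genes, or other genes that fell, came from that tissue was left open. Col1a2, Col18a1 and Lgals3 were at log2 -1.92, -1.16 and -1.10 (adjusted p from 0.0647 to 0.131).

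The lists of glial reactivity and homeostasis were not called by camera in the main fit. The form of fry that counts changes in either direction gave an unadjusted p of 0.00099 for gliosis and 0.0018 for homeostasis. Some members thus differed without a common direction. That form does not compare a list with other genes, and the ganglion cell list had a similar p by it (0.0010). Of 23 reactive gliosis genes S100a6 fell (log2 -0.73, adjusted p = 0.0496) and 22 did not pass, with 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.925). Gfap stood higher while Cd44 (log2 -0.57, adjusted p = 0.0647) and the cytokine Lif (log2 -1.28, adjusted p = 0.0738) stood lower. Among 20 genes of Müller glia homeostasis Dbi rose and 19 did not pass (camera adjusted p = 0.803; 1 higher when adjusted over the list alone). With sex as a covariate the homeostasis list was called, but that fit rests on Yap CKO 3 alone. Rlbp1, which encodes the retinaldehyde-binding protein CRALBP, was at log2 -0.31 (adjusted p = 0.158) and Clu at 0.29 (0.195).

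Cell cycle genes did not pass singly. In the G1 list, none of 15 genes passed by edgeR, over all genes or adjusted over the list alone (5 lower and 1 higher at an unadjusted p under 0.05, 4 lower by DESeq2, 0 by limma-voom), and Ccnd1 was at 136 ± 40.9 against 245 ± 43.7 CPM (log2 -0.85, adjusted p = 0.182), Ccnd2 at log2 -1.13 (0.183) and Myc at log2 -0.55 (0.116; camera adjusted p = 0.219 for the list, which was called with all 9 libraries in one fit, adjusted p = 0.0336). In the list of S, G2 and M phase genes, 12 of 17 were positive (camera adjusted p = 0.3001), with Top2a at log2 1.37 and Cdk1 at log2 1.06 but under 1 CPM in both groups (adjusted p = 0.146 and 0.194). Rod genes did not differ as a group (median 0.0035 and mean 0.03, with the list test pointing down at an adjusted p of 0.586), and the spread within groups was wide: Nrl was at 272 ± 232 against 229 ± 156 CPM (n = 3). Without Yap CKO 3 the rod list pointed up (adjusted p = 0.0265), and without Yap CKO 1 or control 2 it pointed down (adjusted p = 0.00557 and 0.0488). It also pointed down with sex as a covariate, for Yap CKO 3 alone against the controls. Lens transcripts were positive for 12 of 12 genes, set by Yap CKO 3, with Cryaa at 200 ± 334 against 2.77 ± 1.55 CPM (log2 6.17, SE 2.72, adjusted p = 0.341). The lens list was not called (camera adjusted p = 0.0547, 0.974 with an estimated correlation), but it was called in 9 of 19 alternatives.

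**Figure D3:**
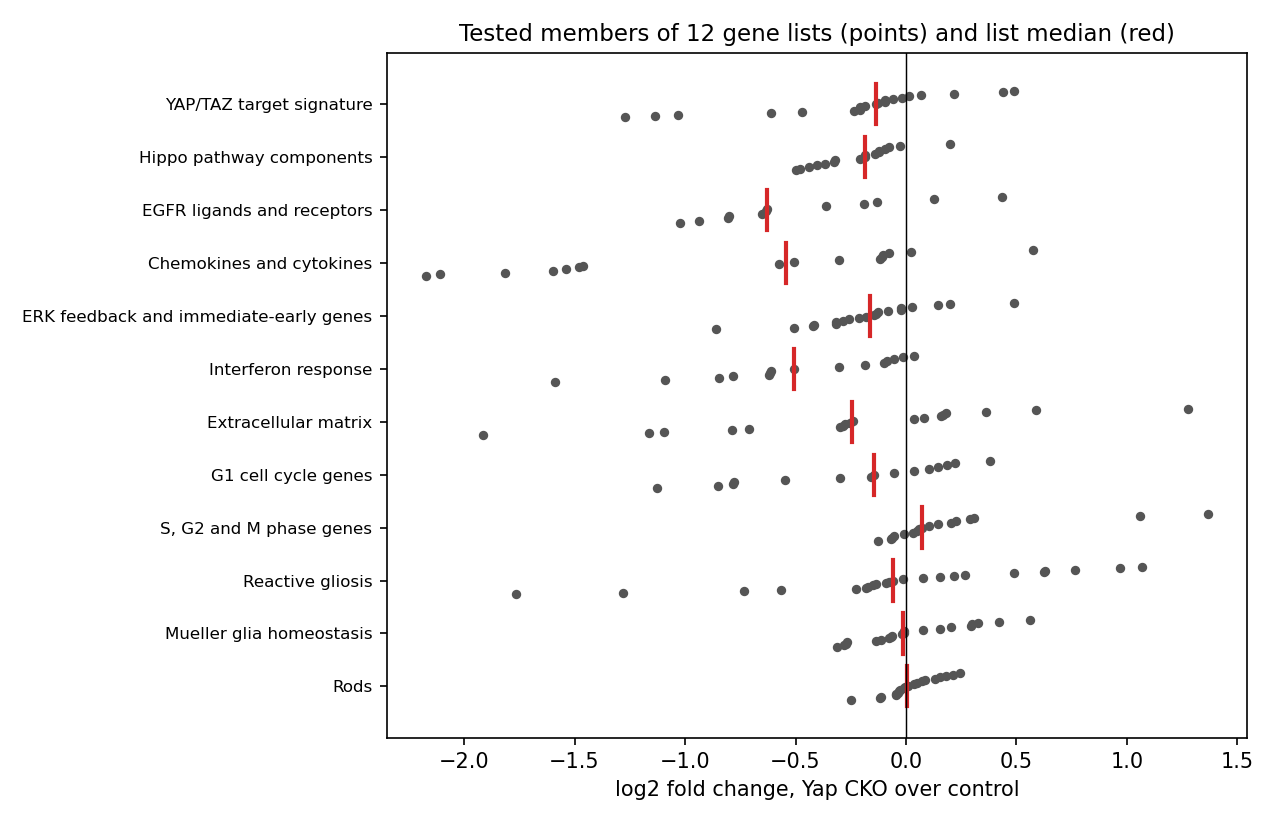
Each point is the log2 fold change (Yap CKO over control) of 1 tested member of the list named at the left, and red lines mark list medians. The EGFR and chemokine lists lie furthest to the left (medians -0.63 and -0.54), whereas the rod list is centred near 0.

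The authors' deposited table for the same comparison listed 231 lower and 74 higher genes, with p-values up to 0.0489, and gave 156 of the 305 an adjusted p under 0.05. Of these 305 genes 302 were tested here, all 302 had the same sign, 254 had an unadjusted p under 0.05 and 27 of the 33 genes passing here were among them. Both analyses used the same libraries, so equal signs are no independent support. The smallest absolute log2 fold change in the deposited table was 0.587, while no fold limit was set here. Of the genes missing from it, Dbi (log2 0.56), Sfxn5 (0.45), Kirrel (-0.58) and Pde1c (-0.50) lie under that size. Their absence is no disagreement. The other missing genes, Slc43a3 and Dsg1a, lie above it. By its name, the deposited comparison also has a limit on FPKM, a read level scaled by gene length, which was not applied here.

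Control retinas at P60 and wild-type C57 retinas at P30 differ in age, floxed allele, tamoxifen, whatever the letters MNU refer to, source series and sex (3 males against 1 male and 2 females), and these cannot be told apart. Depth differed too, and thinning the P60 libraries to the C57 depth, an alternative chosen after seeing the data, kept 6425 of 7202 calls. With that limit, 3655 genes were higher and 3547 lower in control among 15820 tested, and 58.5% of genes had no overlap between groups (10% by chance). Every one of 22 tested reactive gliosis genes rose, also when adjusted over the list alone (median log2 4.60; camera adjusted p = 1.02e-13, adjusted p = 0.209 with an estimated correlation). Lif went from 0.288 to 163 ± 20.1 CPM (log2 9.10), the acute-phase serpin Serpina3n to 364 ± 36.7 CPM (log2 5.09, uncertain because its gene family has near-identical copies), and Cebpd and Cd44 had log2 fold changes of 5.996 and 4.82. At the same time all 20 rod genes fell (20 adjusted over the list alone; median log2 -3.18; camera adjusted p = 1.09e-09, adjusted p = 0.299 with an estimated correlation). The rod transcription factors Nrl and Nr2e3 had log2 fold changes of -3.62 and -4.09, and the G protein subunit Gnb1 went from 8913 ± 636 to 1044 ± 416 CPM. Levels are shares of whole-retina reads. With fewer rod reads, moderate rises of other genes, here and in Yap CKO against C57, can also reflect a larger share of other cells. This was not tested. Of 13 cone genes 11 fell (11 adjusted over the list alone; camera adjusted p = 1.48e-05, adjusted p = 0.264 with an estimated correlation), among them the cone opsins Opn1sw and Opn1mw (log2 -4.80 and -4.72), Gnat2 (-3.28) and Kcne2 (-2.66).

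Of 20 genes of Müller glia homeostasis 9 fell and 3 rose in these whole-retina libraries, the same numbers as adjusted over the list alone, and the list as a whole did not pass by camera (adjusted p = 0.0818; fry adjusted p = 0.000998). Glul, which encodes glutamine synthetase, went from 3946 ± 114 to 902 ± 137 CPM (log2 -2.13), and Abca8a and Gpr37 had log2 fold changes of -3.44 and -2.19, whereas the progenitor factor Sox2 rose (log2 2.14). Among the largest changes, Prss56 rose from 3.48 ± 2.57 to 1759 ± 272 CPM (log2 9.01, SE 0.516), Fosl1 from 0.128 to 156 ± 13.8 CPM (log2 10.28) and the metalloproteinase inhibitor Timp1 from 0.149 to 39.8 ± 11.9 CPM (log2 8.05). Serpinb2 was absent from the C57 counts and at least 217-fold higher in control, computed against a floor of 3 counts over the C57 group. Among the largest drops were also Abca6, Rspo2 and Spc25, with log2 fold changes of -5.45, -5.18 and -4.35. Srp54a (log2 -6.88) has close copies in the genome that can share reads, so its value is uncertain.

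Inflammatory genes rose broadly in control over C57. Of 14 tested chemokines and cytokines 13 rose, also when adjusted over the list alone (camera adjusted p = 1.92e-07; adjusted p = 0.209 with an estimated correlation). Ccl2 had 1 count in the C57 libraries together, which gives a ratio of 5104 with a 95% counting interval from 916 to 2.02e+05, and Ccl7 had none, which gives at least 306-fold against the same floor. Of 15 interferon-stimulated genes 14 rose (15 adjusted over the list alone; camera adjusted p = 1.45e-05, adjusted p = 0.306 with an estimated correlation), with Gbp2, Ifit1 and Irf9 at log2 3.82, 2.98 and 2.72. Complement genes rose in 9 of 12 cases and fell in 2, as also adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.306 with an estimated correlation), among them C5ar1 (log2 4.38) and C3 (3.42).

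The groups linked to Yap were higher in control than in C57, as shares of whole-retina reads. Yap1 rose 2.30-fold, from 25.6 ± 3.60 to 59.1 ± 4.49 CPM (n = 3, log2 1.20, adjusted p = 0.000348), and Wwtr1 from 22.3 ± 3.23 to 67.3 ± 2.92 CPM (log2 1.59). Of 21 YAP/TAZ targets 13 rose and 2 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.000789; adjusted p = 0.209 with an estimated correlation), including Ccn1, Axl and Myof with log2 fold changes of 3.85, 3.57 and 3.24. Of 17 Hippo components 9 rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 0.00997; adjusted p = 0.264 with an estimated correlation). Among them, Tead1 and Amotl1 had log2 fold changes of 1.996 and 1.91. EGFR ligands and receptors rose in 8 of 12 cases and fell in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00347; adjusted p = 0.209 with an estimated correlation). Among them, Hbegf was at log2 3.49, Tgfa at 1.93 and Nrg1 at 1.32. Of 20 ERK feedback and immediate-early genes 14 rose and 3 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.000418; adjusted p = 0.255 with an estimated correlation). Genes of G1 rose in 11 of 15 cases and fell in 1, as also adjusted over the list alone (camera adjusted p = 0.000197; adjusted p = 0.209 with an estimated correlation), among them Myc (log2 7.16), Cdk6 (2.84), Ccnd1 (2.59) and E2f1 (2.21).

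The p53, antioxidant, cell death and endoplasmic reticulum stress genes were higher as lists. The list of 11 heat shock genes was not called, with 3 genes higher and 3 lower (camera adjusted p = 0.992). Of 20 p53 targets 12 rose and 3 fell, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.209 with an estimated correlation), with Eda2r, the cell cycle inhibitor Cdkn1a and Phlda3 at log2 5.81, 4.10 and 3.63. Antioxidant genes and metallothioneins rose in 7 of 12 cases and fell in 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00620; adjusted p = 0.255 with an estimated correlation), with Hmox1, Mt2 and Mt1 at 4.80, 4.68 and 3.65. Cell death genes rose in 8 of 14 cases and fell in 2, as also adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.255 with an estimated correlation), including Casp8, Bid and Ripk1 at 3.03, 2.55 and 2.05. Matrix genes rose in 12 of 18 cases and fell in 2, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.000145; adjusted p = 0.264 with an estimated correlation), including Lgals3 at log2 5.31. Genes of the endoplasmic reticulum stress response rose in 6 of 15 cases, also when adjusted over the list alone (camera adjusted p = 0.0209; adjusted p = 0.437 with an estimated correlation), and Wnt pathway genes in 6 of 14, again the same when adjusted over the list alone (camera adjusted p = 0.0275; adjusted p = 0.264 with an estimated correlation). Pigment epithelium genes fell in 9 of 12 cases and rose in 1, as also adjusted over the list alone (camera adjusted p = 0.00209; adjusted p = 0.209 with an estimated correlation), and all 5 red blood cell genes fell, 5 also when adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.413 with an estimated correlation). Without C57 1 the p53, complement, Hippo, endoplasmic reticulum stress and cell death lists were not called (adjusted p = 0.0530 each), nor were the red blood cell (0.0529) and Wnt (0.0517) lists. Without the unnumbered C57 library the cell death (0.0708) and Wnt (0.0541) lists were lost, and without control 2 the endoplasmic reticulum stress list (0.0757). The cell death list was also lost with the CPM filter (0.2198) or after thinning (0.0899), and the Wnt list with the CPM filter (0.0898). Thinning the P60 libraries to the C57 depth left 3292 higher and 3255 lower genes.

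Set against C57, the Yap CKO retinas had higher gliosis and lower photoreceptor transcripts, while Yap1 did not differ detectably from its wild-type level (19.4 ± 4.33 against 25.8 ± 3.56 CPM, n = 3, log2 -0.41, SE 0.196, adjusted p = 0.126). Wwtr1 rose from 22.4 ± 3.19 to 48.0 ± 2.58 CPM (log2 1.096). In all, 3217 genes were higher and 3202 lower among 15840 tested, and 55.0% had no overlap (10% by chance). Of 22 gliosis genes 20 rose, also when adjusted over the list alone (camera adjusted p = 6.60e-15; adjusted p = 0.242 with an estimated correlation). Lif stood at log2 7.82 and Timp1 at 8.66. Other large rises were Fosl1 (9.40), Prss56 (8.81), Myc (6.60) and Icam1 (5.35). Of 20 rod genes 12 fell and all 20 were negative, with 19 lower when adjusted over the list alone (camera adjusted p = 1.95e-07; adjusted p = 0.425 with an estimated correlation). Of 13 cone genes 8 fell, or 9 adjusted over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.280 with an estimated correlation), among them Opn1mw (-5.64), Opn1sw (-4.57) and Kcne2 (-2.71). Abca6 had a log2 fold change of -5.20. Without C57 2 the counts were 2007 higher and 1979 lower, and without Yap CKO 2 they were 2024 and 1881. Opn1sw missed the threshold without C57 1 (adjusted p = 0.0930), the unnumbered C57 library (0.107) or Yap CKO 2 (0.0895), and without a count filter (0.0835).

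Chemokine, interferon and complement genes were also higher in Yap CKO than in C57. Of 12 chemokines and cytokines 11 rose, also when adjusted over the list alone (camera adjusted p = 1.82e-07; adjusted p = 0.123 with an estimated correlation), and Ccl2 had a ratio of 1175 with a counting interval from 211 to 46423. Interferon-stimulated genes rose in 12 of 15 cases, or 13 adjusted over the list alone (camera adjusted p = 1.38e-05; adjusted p = 0.280 with an estimated correlation), and complement genes in 7 of 11 with 1 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00499; adjusted p = 0.280 with an estimated correlation). Of 21 YAP/TAZ targets 12 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.00631; adjusted p = 0.400 with an estimated correlation). Axl stood at log2 2.52 and Ccn1 at 2.57. The Hippo and EGFR lists did not pass (camera adjusted p = 0.132 and 0.0527, and 0.400 and 0.280 with an estimated correlation). Of their members 9 of 17 and 5 of 12 rose, while 1 and 2 fell. The EGFR list was called without Yap CKO 1 (adjusted p = 0.0447) or Yap CKO 2 (0.0475), with the CPM filter (0.0155), without a count filter (0.0156), after thinning (0.0379) and by fry (0.000233). The Hippo list was called without a count filter (0.0187) and by fry (0.0102). Egfr itself was at log2 0.06 (adjusted p = 0.819). ERK feedback and immediate-early genes rose in 13 of 20 cases and fell in 3, as also adjusted over the list alone (camera adjusted p = 0.000780; adjusted p = 0.280 with an estimated correlation), and G1 genes rose in 11 of 15 and fell in 1, again the same adjusted over the list alone (camera adjusted p = 0.000619; adjusted p = 0.352 with an estimated correlation). Ccnd1 was at 120 ± 35.7 against 36.1 ± 4.28 CPM (log2 1.73).

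Matrix genes rose in 11 of 18 cases, or 13 adjusted over the list alone (camera adjusted p = 0.000199; adjusted p = 0.416 with an estimated correlation). Of 20 p53 targets 11 rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00733; adjusted p = 0.280 with an estimated correlation). The cell cycle inhibitor Cdkn1a was at log2 3.98. Antioxidant genes rose in 7 of 12 cases and fell in 2, as also adjusted over the list alone (camera adjusted p = 0.00691; adjusted p = 0.280 with an estimated correlation). Hmox1 was at log2 5.38. Cell death genes rose in 8 of 14 cases and fell in 1, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0267; adjusted p = 0.280 with an estimated correlation). Endoplasmic reticulum stress genes rose in 7 of 15 cases and Wnt pathway genes in 5 of 14, with the same numbers adjusted over the list alone (camera adjusted p = 0.00631 and 0.0266; adjusted p = 0.425 and 0.422 with an estimated correlation). Heat shock genes did not move as a list (4 of 11 higher and 3 lower, camera adjusted p = 0.956). Without C57 1 the cell death list was lost (adjusted p = 0.0565), as it was without the unnumbered C57 library (0.0593), Yap CKO 2 (0.0647) or Yap CKO 3 (0.0833), with the CPM filter (0.379) and after thinning (0.147). The Wnt list was lost without the unnumbered C57 library (0.0593) or Yap CKO 3 (0.152), with the CPM filter (0.0964), with all 9 libraries in one fit (0.0714) and after thinning (0.0562). Ganglion cell genes rose in 4 of 11 cases, also adjusted over the list alone (camera adjusted p = 0.0245; adjusted p = 0.280 with an estimated correlation), a call lost without Yap CKO 3 (0.0527). Pigment epithelium genes fell in 5 of 12 cases and rose in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00832; adjusted p = 0.534 with an estimated correlation; fry adjusted p = 0.0681), and all 5 red blood cell genes fell, 5 also adjusted over the list alone (camera adjusted p = 0.00983; adjusted p = 0.425 with an estimated correlation).

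Most genes lowered in Yap CKO were also higher in control than in C57. How much of this overlap came from the shared control libraries remains open. Of the 30 genes that fell in Yap CKO against control, 26 were among the 3655 that rose in control against C57, where independent lists would share 6.99 of the 15697 genes tested in both (Fisher's exact test, odds ratio 21.6, two-sided p = 3.27e-13). Fosl1, Icam1, Hbegf, Ccl2, Vcam1 and Yap1 were among the 26. The control libraries enter both comparisons with opposite sign. In 30 simulations of unchanged groups, lists of the same sizes taken by smallest p shared 16 to 26 genes (mean 21.4). Both simulated lists hold noise alone, whereas the 3655 genes passed the threshold. The simulations therefore cannot say how many of the 26 the shared controls gave. The p above does not account for the shared controls. Across genes, which are not independent replicates, the log2 fold changes of the comparisons correlated at -0.20 (-0.48 in the simulations). Their covariance was -0.0795 against -0.0343 (-0.0398 to -0.0313 over the simulations). With 3 controls, they cannot be split into parts of at least 2 libraries, so part of any excess may come from the shared controls. Control and Yap CKO shared 2824 higher and 2814 lower genes against the same C57 libraries (722 and 725 for independent lists; at most 1661 and 1606 for lists of the same sizes in the simulations), with 7 genes called in opposite directions, a correlation of 0.96 (0.55 simulated) and a covariance of 1.42 (0.0399 simulated). The overlap of 26 was 0 without control 1 or control 2, 1 without Yap CKO 2, 2 without Yap CKO 1, 47 without control 3 and 366 without Yap CKO 3.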

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

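The rod covariate, the sex covariate and the bias-adjusted deviances were chosen after seeing the data. The sex covariate leaves Yap CKO 3 alone against the controls, so its counts rest on 1 library. For Yap CKO against control, with 3 higher and 30 lower genes, requiring a 1.5-fold change left 1 higher, an unadjusted p with 1.5-fold gave 158 and 340, and an adjusted p under 0.01 gave 0 and 0 by edgeR (2950 unadjusted). RLE scaling, TMM without the 50 highest genes, the CPM filter, limma-voom and the bias-adjusted deviances each gave 1 and 14, upper-quartile scaling 3 and 14, no filter 83 and 260, DESeq2 364 and 558, one fit over 9 libraries 3 and 57, the rod covariate 747 and 897, and the sex covariate 43 and 24. Leaving out 1 library gave 0 to 656 higher and 0 to 817 lower genes. Yap1 was at -1.62 with the replicate block (adjusted p = 0.0732), -1.35 with the sex covariate and -1.75 to -1.43 without 1 library. An adjusted p under 0.01 left 2259 higher and 2298 lower genes in control and 1791 and 1734 in Yap CKO against C57, where leaving out 1 library gave 2007 to 4234 and 1881 to 3779. The overlap of 26 genes with those higher in control became 231 (unadjusted), 0 (0.01), 12 (RLE, upper quartile, TMM without 50, CPM filter, voom, bias-adjusted), 171 (no filter), 339 (DESeq2), 47 (all 9), 432 (rod), 15 (sex) and 0 to 366 (leave-one-out). The 27 genes shared with the authors' deposited table became 254, 0, 13 (the same 6 settings), 103, 217, 47 and 169 (rod), and 0 to 123. Of 7, 19 and 18 lists called in Yap CKO against control, control against C57 and Yap CKO against C57, an estimated correlation kept 0, 0 and 0. Fry called 2 in the first and the sex covariate 12, and leaving out 1 library gave 12 to 19 in the second. Bipolar, pigment epithelium and matrix lists turned direction with the sex covariate (adjusted p = 0.0115, 0.00105 and 0.971), and rods without Yap CKO 3 (0.0265). Leaving out 1 library gave the rod list adjusted p from 0.00557 to 0.736. The cause was not tested. The sex covariate ended the call of the YAP/TAZ targets. Replicates with the same number correlated at 0.392, -0.0282 and 0.0455, and those with different numbers at -0.447 to 0.356. With 3 replicates these values neither show nor exclude pairs. No block was possible against C57, where 1 column matches no sample description. The C57 depth limits what can be seen of rare transcripts in that group.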

Other observations

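Several further gene groups had members that differed between control and C57, while camera with the count filter did not call the list. Among Notch pathway genes 4 of 13 rose and 4 fell (camera adjusted p = 0.665), with the receptor Notch1 at log2 1.88 and the ligand Jag1 at -1.91. Among reprogramming and neurogenic factors 7 of 17 rose and 2 fell (camera adjusted p = 0.122, without a count filter 0.0284, fry adjusted p = 0.000961): the proneural factor Neurog2 rose from 2.05 ± 0.804 to 13.8 ± 3.11 CPM, whereas Insm1 and Otx2 had log2 fold changes of -2.43 and -1.49. Microglia genes split, with 6 of 19 higher and 3 lower (camera adjusted p = 0.876). Cd68, a lysosomal marker of phagocytes, had a log2 fold change of 3.39, and the homeostatic microglia genes P2ry12 and Tmem119 had -4.41 and -2.64. Of 12 bipolar cell genes 1, Trpm1, rose (log2 0.58) and 3 fell, among them Prkca (log2 -1.07; camera adjusted p = 0.280, fry 0.0185), and of 11 ganglion cell genes 5 rose, among them Pou4f1 (log2 0.52), and 0 fell (camera adjusted p = 0.0929, without a count filter 0.0103, fry 0.00594). Replication genes Mcm6 and Mcm3 rose (log2 0.89 and 0.64), while the mitotic kinase Plk1 fell (log2 -2.56; list of S, G2 and M phase genes, camera adjusted p = 0.270, fry 0.0185). In the heat shock list Bag3 rose (log2 2.38) and Hsp90aa1 fell (log2 -1.42).

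For the genes past the threshold, the rod level test was chosen after the result was seen, and the split and sex tests before. In each comparison 1 of the 10 splits of the 6 libraries, the real one, gave as many genes. The highest other split gave 1 gene against 33 for Yap CKO against control (1961 against 2950 unadjusted), 0 against 7202 for control against C57 and 0 against 6419 for Yap CKO against C57, and 10 splits are too few to decide. With the rod level as a covariate the log2 fold changes of the 33 genes had a median ratio of 1.01 to those without it (0.962 to 1.05). The rod level varied widely within both groups and overlapped between them, so adding it could move these values little. The ratio therefore does not decide whether uneven rod content contributed. Among 1406 autosomal genes called without Yap CKO 3, the male Yap CKO 3 showed a median of 0.401 of the change in the 2 females, with 78.7% on the same side. Both differences were taken from the same controls, and the genes were picked for the change in the females. The values expected without any effect are therefore not known, and sex remains open beside the Yap deletion.

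For Raxos1, both tests were chosen after the result was seen. Its log2 fold change exceeded that of Rax by 2.84 (SE 0.418), which argues against a constant share of Rax reads on the opposite strand as the source. Rax had far more counts than Raxos1 (1611 against 139 in Yap CKO 1). A change confined to the stretch of Rax that overlaps Raxos1 was therefore not excluded. The lowest library with the Rax-CreERT2 allele stood at 3.13 CPM and the highest without it at 1.29 CPM, a ratio of 2.43. This would be consistent with an effect of the inserted allele on its own locus, but no library carries the allele without the Yap deletion, so both remain open.

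For the genes at least 4-fold lower in the authors' deposited table, the marker lists were chosen after the pattern was seen, the ciliary list after the connective one, and the test of one source after its result was seen. The authors' deposited table holds 21 such genes, with a median log2 fold change of -2.29, and 2 of them, Ccl2 and Mylk2, passed here; Slc26a4 was at -5.08 and Cldn2 at -3.58 here, named after their values were seen. Connective tissue markers had a median of -0.032, with 6 of 12 negative, so these markers did not fall as a set. Among them Dcn and Comp lay under 1 CPM in every library and Col5a1 was at log2 -1.56, so that tissue was not excluded. Ciliary epithelium markers had a median of -0.62, with 13 of 15 negative, and remain open. The ratio of control 3 to control 1 had a median log2 of -1.46 for the 21 genes against 0.02 for 14208 genes, with an SD of 0.551 against 0.276, so a single source in uneven amounts also remains open. An effect of the Yap deletion on these genes was not excluded.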
